A study of Mus musculus with 139 samples.

How the data were processed

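Lung tissue of male mice, written C57BL/J6 in the labels, was profiled on 139 Affymetrix arrays, a column for each array. Mice had received dispersion medium (DM), multi-walled carbon nanotubes (MWCNT) at 1, 10, 40 or 80 µg, or crocidolite asbestos at 120 µg, and lungs were taken 1, 6 or 12 months later, which gives 18 groups. Each array was placed in its group by the label that states treatment, dose and time. The labels number the mice, so the replicates are separate animals, apart from mouse 101 (1 µg, 1 month), which has 2 arrays. Those arrays correlated at 0.976 over all genes, below the median of 0.982 for other pairs of the group (0.968 to 0.991). Their log2 values differed with an SD of 0.531, against a median of 0.452 for other pairs, and Acta1, a skeletal muscle actin, was at 3.00 in one and 8.74 in the other. The values thus do not show that they come from a single mouse, and the mouse number in the labels was followed. They were averaged and counted once, leaving 138 mice. Within a group, replicate numbers follow the order of deposition and only name a mouse.

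The deposited values are on a log2 scale. RMA (background correction, quantile normalization and summary over probes), oligo and limma are named in the submitters' processing notes, per the labels, and their versions and roles are not given in the sources used here. The scale was taken from the notes and from the values, which ran from -0.05 to 13.276 with array medians between 4.009 and 4.336. The genome build is not given in the sources used here, so no coordinates are reported. All sample columns of the table were used. Of 41345 features, 23521 were paired with a single gene symbol, 1814 with several and 16010 with none. Symbols came from the platform annotation and were checked through Entrez numbers against RefSeq gene records of assembly GRCm38.p6, where 23328 of the single-symbol features matched and 0 symbols changed. For genes with several features the one with the highest mean over all arrays was kept, which set 1341 aside and left 22180 genes. Spp1, meant as a panel gene, had no feature paired with it alone and is not analysed here.

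The comparisons, the main test, the gene lists, the rule for named genes and the main alternatives were chosen before the data were examined. One linear model with a mean per group over all arrays (120 residual degrees of freedom) was fitted in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 22180 genes were counted as higher or lower, and every adjusted p given for a gene is from this limma test, two-sided. Differences are log2 values, treated minus control, with the standard error (SE) of the fitted contrast, and group levels are means with SD. Each exposed group was compared with DM of the same time, 80 µg MWCNT with crocidolite, and the 12-month effect with the 1-month effect as an interaction. The dose trend is the slope of the 5 group means on the log2 of dose in µg plus 1. Tables were handled with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9.

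Genes named are, for 80 µg and crocidolite against DM, the 8 highest and 8 lowest by log2 difference among those past the test and the 2 largest per gene list, and for other comparisons the 3 highest and 3 lowest. Predicted genes and olfactory receptors were passed over by that rule. Genes named by the rule in a comparison are also given in others. The remaining genes are panel genes such as Col1a1, markers of squamous epithelium or muscle, or genes that the text says were chosen after their values were seen.

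Gene lists (44, with 646 of 720 members measured) were tested with camera in limma, two-sided, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the 44 lists of a comparison. Among 50 draws of unchanged groups of 8 and 8 arrays made from the residuals, that test called a median of 7 lists and up to 22. Camera with a correlation estimated from the residuals called a median of 0, with any call in 1 of 50 draws, and fry, which tests whether the genes of a list move on balance in one direction, a median of 0, with any call in 5 of 50. These draws were fitted on their own arrays, with fewer residual degrees of freedom than the 120 of the model. Their rates of calls need not hold for the lists reported. With that limit, the lists described in the results lead with those that also passed with the estimated correlation.

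The model was tested on simulated data with 200 of 22180 genes changed. For 80 µg against DM at 1 month it recovered 63% of genes changed 1.5-fold and 95% of those changed 2-fold. For the difference in time of the 80 µg effect the shares were 28% and 72%. Noise was normal and independent between genes, without the outlying arrays of the real data, so shares in the real data can be lower. The number of arrays limits the precision.

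Alternatives were other scalings (quantile normalization, centring on array medians), a filter on dim genes, other choices of feature, the samples in the fit, array weights, trended and robust moderation, stricter thresholds, accession order as a natural spline with 3 degrees of freedom, and leaving out each crocidolite array of 1 month in turn. Some array titles hold the word replacement, which the labels do not explain. It was tried as a covariate and arrays with and without it were also analysed apart. Leaving out 3 sets of doubtful arrays and a cardiac muscle covariate were added after the data were seen.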

Results

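Gene expression was measured in whole lung of mice after a single pharyngeal aspiration, in which a droplet placed behind the tongue is breathed in. DM, a buffered saline with glucose, albumin and a surfactant phospholipid, was the vehicle, MWCNT are rigid carbon fibres, and crocidolite is an amphibole asbestos used as a reference fibre. There were 8 mice per group, except 6 at 1 µg and 12 months, 5 with crocidolite at 1 month and 7 with crocidolite at 12 months. The study asked how inflammatory and fibrotic responses and expression changed with increasing MWCNT dose up to 12 months.

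Clca1 of mucous cells and the macrophage genes Mmp12, Retnla and Gpnmb rose at 1, 6 and 12 months in lungs given 80 µg MWCNT and in lungs given crocidolite. At 1 month 374 genes were higher and 24 lower with 80 µg, at 6 months 178 and 29, and at 12 months 35 and 4. This order depended on the arrays, since among those without the word replacement in the title the 80 µg count was largest at 12 months. Crocidolite gave 649 higher and 628 lower genes at 1 month, 321 and 495 at 6 months, and 955 and 479 at 12 months. At 1 µg limma called 0 genes at each time. Genes at an unadjusted p under 0.05 numbered 437, 1249 and 595 at 1, 6 and 12 months. A share of 0.05 of the 22180 genes would reach that p by chance on average, and only the 6-month count is above it. Genes are not independent, so such counts can lie well above or below that share without any effect, and 1249 is no test of one. Of the 6-month arrays at 1 µg, replicate 7 stood far above the others in macrophage genes such as Mmp12. Replicates 3 and 8 were high in Krt4, a keratin of squamous epithelium. Replicates 4 and 6 correlated less with other arrays (medians 0.925 and 0.923). Trended and robust moderation called 2 genes at 1 µg and 6 months and 0 at the other 2 times.

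**Figure D1:**
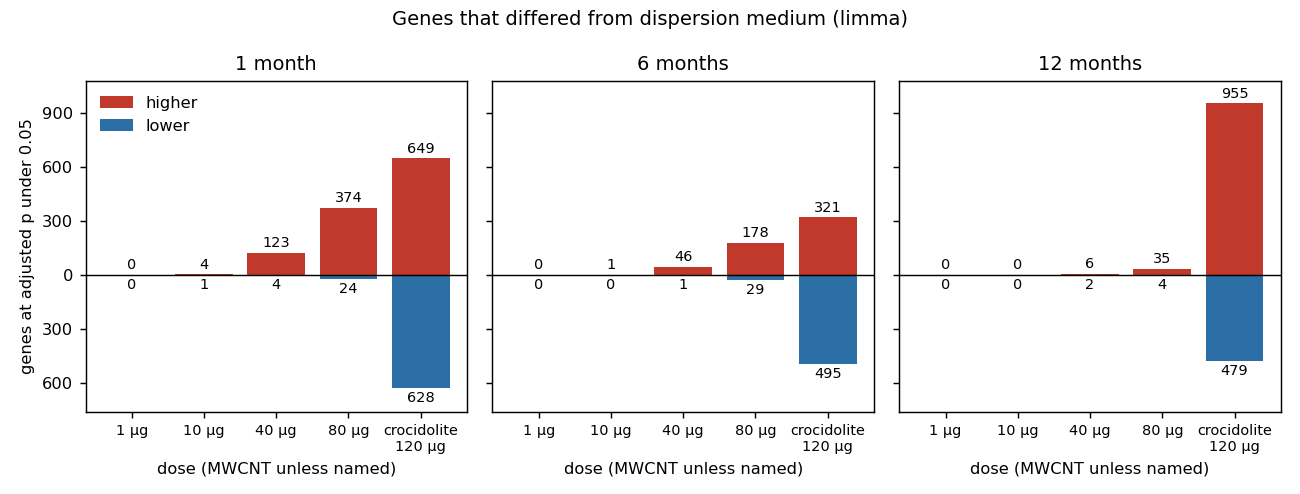
Number of genes (vertical axis) higher (red, upward) and lower (blue, downward) than in DM at an adjusted p under 0.05, for each dose (horizontal axis) at 1, 6 and 12 months. Counts for MWCNT are largest at 80 µg, with 374 higher genes at 1 month and 35 at 12 months, and crocidolite reaches 955 higher genes at 12 months.

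One month after 80 µg MWCNT, Clca1, a protein secreted by mucous cells of the airway, rose by 6.36 ± 0.63 (SE; adjusted p = 3.5e-14), with 8 of 8 mice above every DM mouse. Chil4, a chitinase-like protein of type 2 inflammation, rose by 5.20 ± 0.58, and Retnla, a marker of alternatively activated macrophages, by 3.68 ± 0.31. Mmp12, the macrophage elastase, rose by 3.87 ± 0.35 and Gpnmb, a glycoprotein of lipid-laden macrophages, by 3.13 ± 0.32, each in 8 of 8 mice. Slc26a4, an anion exchanger of airway epithelium, rose by 3.32, Rnase2a, an eosinophil-associated ribonuclease, by 3.18 and Fcgbp, a mucus protein, by 3.03. Among the 24 lower genes were Fcna, a ficolin of innate immunity (-1.08 ± 0.31, adjusted p = 0.0378), Ces1g, a carboxylesterase (-0.92), Pon1, a lipoprotein-associated esterase (-0.76), and Adm, the vasodilator adrenomedullin (-0.78).

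By list, 11 of 14 mucous cells genes rose at 1 month with 80 µg, also 11 adjusted over the list alone (median 1.53, adjusted p = 2.34e-06 with an estimated correlation). The CC chemokines had 8 of 14 higher, 8 adjusted over the list alone (adjusted p = 0.000179 with an estimated correlation), with Ccl3 at 1.76 ± 0.23 and the eosinophil attractant Ccl11 at 1.45 ± 0.24. In the foam-cell-type macrophages list 12 of 20 rose, 14 adjusted over the list alone, among them the lipid receptor Trem2 at 2.00 ± 0.24 (adjusted p = 5.58e-05 with an estimated correlation). In the lysosome list 13 of 21 rose, 17 adjusted over the list alone, led by Ctsk, a collagen-degrading cathepsin, at 2.80 ± 0.26 (adjusted p = 0.000103 with an estimated correlation). The type 2 immunity list had 8 of 18 higher, 9 adjusted over the list alone, with a median of 0.27 against a mean of 1.19. Among acute phase proteins 6 of 14 rose, 7 adjusted over the list alone, with serum amyloid Saa3 at 2.95 ± 0.47 and Lcn2, an iron-binding protein, at 1.60 ± 0.20. The complement list had 7 of 15 higher, 8 adjusted over the list alone, and cell cycle 7 of 25, 17 adjusted over the list alone. In type 2 alveolar epithelium 8 of 16 rose, 12 adjusted over the list alone, with surfactant protein Sftpd at 0.93 ± 0.11. These 5 lists passed with an estimated correlation (adjusted p from 6.71e-07 for type 2 immunity to 0.00072 for cell cycle). The matrix proteases and inhibitors list had 6 of 22 higher, 10 adjusted over the list alone (adjusted p = 0.000566 with an estimated correlation), with the protease inhibitor Timp1 at 1.28 ± 0.20. The p53 targets list passed as a whole with 0 of 12 genes called by limma over all genes and 3 adjusted over the list alone (adjusted p = 0.023 with an estimated correlation).

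The 398 genes of 80 µg at 1 month were 1.79% of the genes tested. Some array titles hold the word replacement, which the labels do not explain. Arrays without it called 0.343% of genes and arrays with it 0.667%, and with the word as a covariate the share was 1.8%. The skeletal muscle list had a median of -0.92 in this comparison, with 0 of 11 genes called and 0 adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). Acta1 of this list was at 10.40, 9.31 and 7.11 in DM replicates 2, 8 and 1 and at 9.12 in replicate 4 of 80 µg. No other array of these groups was above 5.02. How far these arrays set the median of the list was not tested. Median, mean and test had one sign in each list that passed camera, while among the others the neutrophils list had a median of -0.09 and a mean of 0.07 with 80 µg at 1 month.

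At 6 months after 80 µg, Clca1 stayed higher by 5.18 ± 0.63 (adjusted p = 2.07e-09), Retnla by 3.08 ± 0.31, Mmp12 by 2.92 ± 0.35, Chil4 by 2.84 ± 0.58 and Gpnmb by 2.47 ± 0.32. For Clca1, Mmp12 and Gpnmb 7 of 8 mice were above every DM mouse. Of immunoglobulin genes, Ighv1-54 rose by 2.56 ± 0.60, Iglv1 by 2.37 ± 0.44 and Jchain, the joining chain of secreted antibodies, by 2.35 ± 0.46, after 2.10 ± 0.46 at 1 month. Lower genes included Gria1, a glutamate receptor subunit (-0.81 ± 0.16, adjusted p = 0.000607), Adm (-0.80 ± 0.19), the growth factor receptor Fgfr4 (-0.60 ± 0.14) and Lef1, a transcription factor of Wnt signalling (-0.54 ± 0.14).

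The mucous cells list had 10 of 14 higher at 6 months with 80 µg, 11 adjusted over the list alone (adjusted p = 8.53e-06 with an estimated correlation). Among foam-cell-type macrophages genes 11 of 20 rose, 14 adjusted over the list alone, and among CC chemokines 8 of 14, 9 adjusted over the list alone (adjusted p = 1.03e-05 and 4.42e-05 with an estimated correlation). The plasma cells list had 2 of 11 higher, 3 adjusted over the list alone (adjusted p = 0.0134 with an estimated correlation), with Tnfrsf17, a receptor of antibody-secreting cells, at 0.94 ± 0.23. The interferon-stimulated genes passed with 0 of 17 called by limma over all genes and 3 adjusted over the list alone (adjusted p = 0.0345 with an estimated correlation). The lymphoid tissue stroma and germinal centres list was lower, with 0 of 11 called over all genes and 3 lower adjusted over the list alone (median -0.12, adjusted p = 0.0248 with an estimated correlation). The B cells list had 0 of 14 called over all genes and 9 lower adjusted over the list alone, and its call was lost (adjusted p = 0.0721 with an estimated correlation). Centring arrays on their medians moved the share of higher genes among those called from 86% to 72%. Fitted on the groups compared alone 24 genes passed, and with array weights 2.34% of genes against 0.933%. Arrays without the word replacement gave 59 genes, with the word as a covariate 207, and too few arrays with it were in the DM group for a value.

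At 12 months after 80 µg, Clca1 was higher by 4.70 ± 0.63 (adjusted p = 1.28e-07), Mmp12 by 2.89 ± 0.35, Gpnmb by 2.30 ± 0.32 and Retnla by 2.26 ± 0.31, each in 8 of 8 mice above every DM mouse. Igh-VS107, an immunoglobulin heavy chain segment, rose by 1.95 ± 0.40, Ctsk by 1.42 ± 0.26, Cd177, a neutrophil surface protein, by 1.42 ± 0.23 and Trem2 by 1.11 ± 0.24. Cd3d, a subunit of the T cell receptor complex, fell by 0.86 ± 0.19 (adjusted p = 0.019), Bend5 by 0.53 and Swap70, a signalling protein of B cells, by 0.34. The mucous cells list had 5 of 14 higher, 12 adjusted over the list alone (adjusted p = 0.00491 with an estimated correlation). Of acute phase proteins 1 of 14 rose, 4 adjusted over the list alone (adjusted p = 0.0413 with an estimated correlation). T cells were lower, with 1 of 18 called over all genes and 8 adjusted over the list alone (median -0.36, adjusted p = 0.0231 with an estimated correlation). In foam-cell-type macrophages 4 of 20 rose, 10 adjusted over the list alone, and the call of the list was lost (adjusted p = 0.0705 with an estimated correlation). The share of genes called was 0.965% in arrays without the word replacement, among them 3 of 80 µg, and 0.0225% in arrays with it, among them 5 of 80 µg, of which 2 were high in Krt4, a keratin of squamous epithelium. It was 0.176% in all arrays and 0.203% with the word as a covariate, and the difference between the subsets was not tested. Centring moved the share of higher genes among those called from 89.7% to 75.8%.

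**Figure D2:**
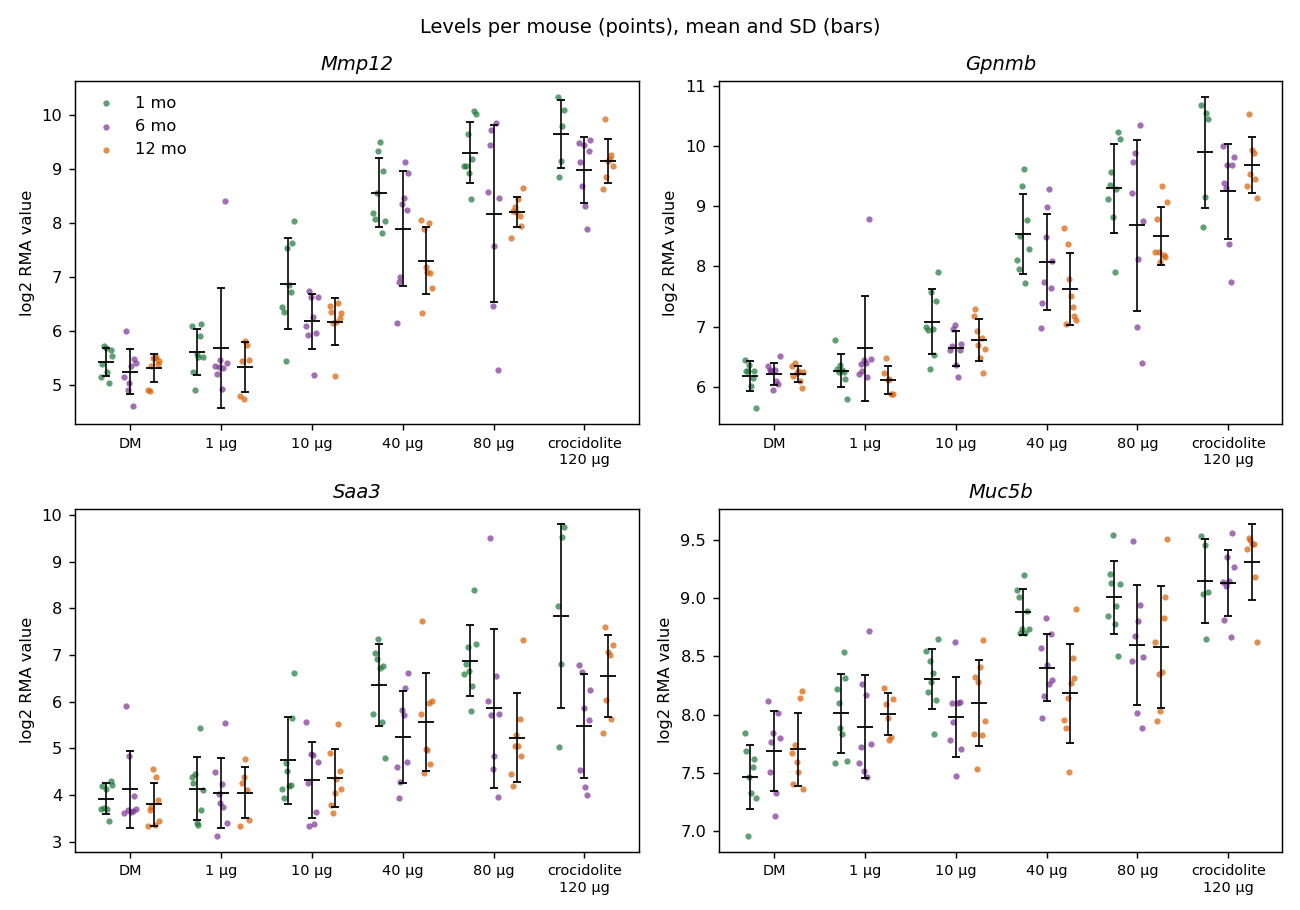
Log2 level (vertical axis) of Mmp12, Gpnmb, Saa3 and Muc5b in each mouse (points) by treatment (horizontal axis) and time (colour), with the mean and SD of each group as black bars. Mmp12 had a mean of 5.43 in DM and 9.30 with 80 µg at 1 month, and 5.31 and 8.20 at 12 months.

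At 10 µg and 1 month Clca1 was higher by 4.50 ± 0.63 (adjusted p = 1.81e-06), with 8 of 8 mice above every DM mouse, Chil4 by 3.27 ± 0.58 and Retnla by 2.01 ± 0.31. The other 2 genes of that comparison, named after their values were seen, were the gel-forming mucin Muc5b (0.84 ± 0.18, adjusted p = 0.0239) and the olfactory receptor Olfr605 (-0.94 ± 0.20, adjusted p = 0.0404). At 10 µg and 6 months the only gene past the test was Retnla (1.80 ± 0.31, adjusted p = 0.000766), where 6 of 100 splits of the arrays called as many genes. At 12 months limma called 0 genes, with 945 at an unadjusted p under 0.05, fewer than chance would give on average. That does not show an absence of change. Mmp12, picked after its values were seen, had a mean of 6.18 ± 0.43 (SD) against 5.31 ± 0.26 in DM. Apart from 1 mouse at 5.16, the 10 µg mice lay at 6.145 to 6.522, above the highest DM mouse at 5.517. The test pools the spread over all groups, and the SD of Mmp12 reached 1.63 with 80 µg at 6 months. The panel genes Col1a1 and Cxcl5 had lower means than in DM. At 40 µg 127 genes passed at 1 month, 4 of them lower, 47 at 6 months, 1 lower, and 8 at 12 months, 2 lower, led by Clca1 at 5.85, 5.08 and 3.70. Ncr1, a receptor of natural killer cells, fell by 0.64 ± 0.17 with 40 µg at 1 month, Ier2, an immediate early gene, by 0.63 ± 0.15 at 6 months, and Ctsw, a cathepsin of cytotoxic lymphocytes, by 0.66 ± 0.15 at 12 months. The mucous cells list passed with 40 µg at 1 month with 10 of 14 higher, 10 adjusted over the list alone (adjusted p = 5.69e-07 with an estimated correlation). At 6 months it passed with 6 of 14, 10 adjusted over the list alone (adjusted p = 0.00176 with an estimated correlation). At 1 µg and 6 months the immediate early genes list was lower, with 0 of 17 called by limma over all genes and 10 adjusted over the list alone (adjusted p = 0.00676 with an estimated correlation). Several arrays of that group stood out, as described with its count of genes, and the list is not reported without them. At 40 µg and 12 months 541 genes differed in arrays without the word replacement and 2 in arrays with it, against 30 with it as a covariate. With array weights the 12-month share was 3.14% of genes for 40 µg and 0.573% for 80 µg, and without 10 arrays of low correlation 0.379% and 0.361%, against 0.0361% and 0.176%, so which dose called more genes at 12 months depended on the setting. Arrays without the word replacement gave 46 genes at 1 month and 30 at 6 months for 40 µg, and 2 at 1 month for 10 µg.

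The dose trend, a slope per doubling of dose plus 1 µg, was past the test for Clca1 at each time (0.95 ± 0.08, 0.83 ± 0.08 and 0.73 ± 0.09 at 1, 6 and 12 months). So it was for Mmp12 (0.63 ± 0.05, 0.47 ± 0.05 and 0.45 ± 0.05). At 1 month 672 genes passed, 567 of them rising with dose, at 6 months 261 rose and 36 fell, and at 12 months 131 rose and 136 fell. Falling genes included Gzma, a granzyme of cytotoxic cells, at 1 month (-0.11 ± 0.03), Gria1 at 6 months (-0.10 ± 0.02) and Cd3d at 12 months (-0.12 ± 0.03). Centring moved the share of rising genes from 84.4% to 71.4% at 1 month, from 87.9% to 74.3% at 6 months and from 49.1% to 68.4% at 12 months. The share called was 3.03%, 1.34% and 1.2% in all arrays, 1.17%, 0.748% and 1.82% in arrays without the word replacement, and 3.15%, 1.59% and 0.996% with it as a covariate. Array weights gave a larger share at each time, and accession order as a spline gave a larger share at 12 months.

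One month after crocidolite (n = 5 against 8), Clca1 was higher by 5.78 ± 0.72 (adjusted p = 6.47e-10), Chil4 by 5.77 ± 0.66, Mmp12 by 4.22 ± 0.40, Rnase2a by 4.21 ± 0.51, Saa3 by 3.91 ± 0.53 and Gpnmb by 3.72 ± 0.36. Arg1, the arginase of alternatively activated macrophages, rose by 2.88 ± 0.38, and Ltf, the iron-binding lactoferrin, by 2.63 ± 0.37. Cidec, a lipid droplet protein, fell by 1.51 ± 0.42 (adjusted p = 0.0145), Pon1 by 1.47 ± 0.19 and Cyp2e1, a cytochrome P450, by 1.45 ± 0.47. The foam-cell-type macrophages list had 13 of 20 higher, 15 adjusted over the list alone, and lysosome 13 of 21, 16 adjusted over the list alone (adjusted p = 8.93e-05 and 0.000173 with an estimated correlation). Of mucous cells genes 11 of 14 rose, also 11 adjusted over the list alone (adjusted p = 7.34e-05 with an estimated correlation). The endothelium list was lower, with 9 of 18 called and 11 adjusted over the list alone (median -0.35, adjusted p = 0.0239 with an estimated correlation), among them the endothelin receptor Ednrb (-1.17 ± 0.17) and the VEGF receptor Kdr (-0.67 ± 0.12). NK and cytotoxic lymphocytes had 5 of 13 lower and 1 higher, 9 and 1 adjusted over the list alone (adjusted p = 0.0153 with an estimated correlation), with Ncr1 at -1.01 ± 0.19 and Gzma at -1.06 ± 0.26. B cells had 9 of 14 lower, 12 adjusted over the list alone, and cardiac muscle 3 of 13 lower, 8 adjusted over the list alone, and both calls were lost (adjusted p = 0.0693 and 0.16 with an estimated correlation).

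Single arrays moved the crocidolite count at 1 month: 1277 genes became 738 without replicate 4 and 627 without replicate 5. Without replicate 2 the count rose. Replicates 4 and 5 had median correlations with other arrays of 0.920 and 0.945, against 0.962 to 0.969 for the rest of the group. Replicate 4 was among the 10 arrays of low correlation. With the word replacement as a covariate 1287 genes passed, in arrays without it 400 and in arrays with it 261. Array weights and leaving out arrays of low correlation also lowered the count, and fitting the groups compared alone lowered it further.

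At 6 months after crocidolite Clca1 was higher by 4.80 ± 0.63, Mmp12 by 3.73 ± 0.35 and Retnla by 3.71 ± 0.31 (adjusted p = 4.63e-19). Dmbt1, a mucosal scavenger protein, was higher by 3.53 ± 0.28 (adjusted p = 2.15e-20) and Gp2, a glycoprotein that binds bacteria at mucosal surfaces, by 3.52 ± 0.26. All 5 were above every DM mouse in 8 of 8 mice. Scgb3a1, an airway secretoglobin, rose by 1.93 ± 0.24. Lower genes included Gria1 (-0.98 ± 0.16), Apln, a peptide of vascular cells (-0.95 ± 0.18), Wnt2, a ligand made by lung mesenchyme (-0.91 ± 0.15), and Glp1r, an incretin receptor (-0.89 ± 0.21). The endothelium list had 10 of 18 lower, 14 adjusted over the list alone (median -0.39, adjusted p = 0.0166 with an estimated correlation), with Ednrb at -0.78 ± 0.15 and the transcription factor Sox18 at -0.59 ± 0.14. The mucous cells list had 11 of 14 higher, 11 adjusted over the list alone, and foam-cell-type macrophages 12 of 20, 14 adjusted over the list alone. Among acute phase proteins 7 of 14 rose, 9 adjusted over the list alone, with the fibrinogen chain Fgg at 1.82 ± 0.30. These 3 lists had an adjusted p from 9.6e-06 to 0.000614 with an estimated correlation. The transitional and basal epithelium list had 2 of 13 higher, 6 adjusted over the list alone (adjusted p = 0.0234 with an estimated correlation), Trp63, a basal cell regulator, at 0.61 ± 0.16. Centring moved the share of higher genes among those called from 39.3% to 50.4%. In arrays without the word replacement 884 genes passed, and 833 with it as a covariate. Without 9 arrays with high Krt4 484 genes differed.

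At 12 months after crocidolite (n = 7 against 8), Dmbt1 was higher by 4.36 ± 0.29 (adjusted p = 2.62e-26), Gp2 by 4.27 ± 0.27, Clca1 by 4.70 ± 0.66, Mmp12 by 3.83 ± 0.36 and Fgg by 3.03 ± 0.32. In each of these 7 of 7 mice were above every DM mouse. Sprr1a, a cornified envelope protein, rose by 1.89 ± 0.46, Cxcl9, an interferon-induced chemokine, by 1.37 ± 0.29 and Hmox1, heme oxygenase, by 0.90 ± 0.14. The 8 lowest genes are genes of striated muscle, with the cardiac myosin Myh6 at -1.60 ± 0.34 (adjusted p = 0.000419), titin Ttn at -1.46 ± 0.37 and cardiac troponin Tnnt2 at -1.42 ± 0.32. The cell cycle list had 18 of 25 higher, 22 adjusted over the list alone (adjusted p = 0.00299 with an estimated correlation). In type 2 alveolar epithelium 12 of 16 rose, 15 adjusted over the list alone, and in foam-cell-type macrophages 14 of 20, 16 adjusted over the list alone (adjusted p = 0.000161 and 0.000307 with an estimated correlation). The interferon-stimulated genes list had 7 of 17 higher, 12 adjusted over the list alone (adjusted p = 0.014 with an estimated correlation). Of ciliated cells genes 7 of 17 rose, 15 adjusted over the list alone, and of plasma cells genes 4 of 11, 5 adjusted over the list alone (adjusted p = 0.0445 and 0.0306 with an estimated correlation). The cardiac muscle list had 10 of 13 lower, 11 adjusted over the list alone, and myofibroblasts and smooth muscle 8 of 12, 9 adjusted over the list alone (adjusted p = 0.0306 for each with an estimated correlation). In the endothelium list 7 of 18 were lower, 12 lower and 1 higher adjusted over the list alone (adjusted p = 0.0368 with an estimated correlation). In the type 1 alveolar epithelium list 0 of 14 genes passed limma, 0 adjusted over the list alone, with a median of 0.11 (adjusted p = 0.927 with an estimated correlation). The share of genes called was 6.47%, with 2.91% in arrays without the word replacement, 1.3% in arrays with it and 7.28% with it as a covariate. Centring moved the share of higher genes among those called from 66.6% to 51%.

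**Figure D3:**
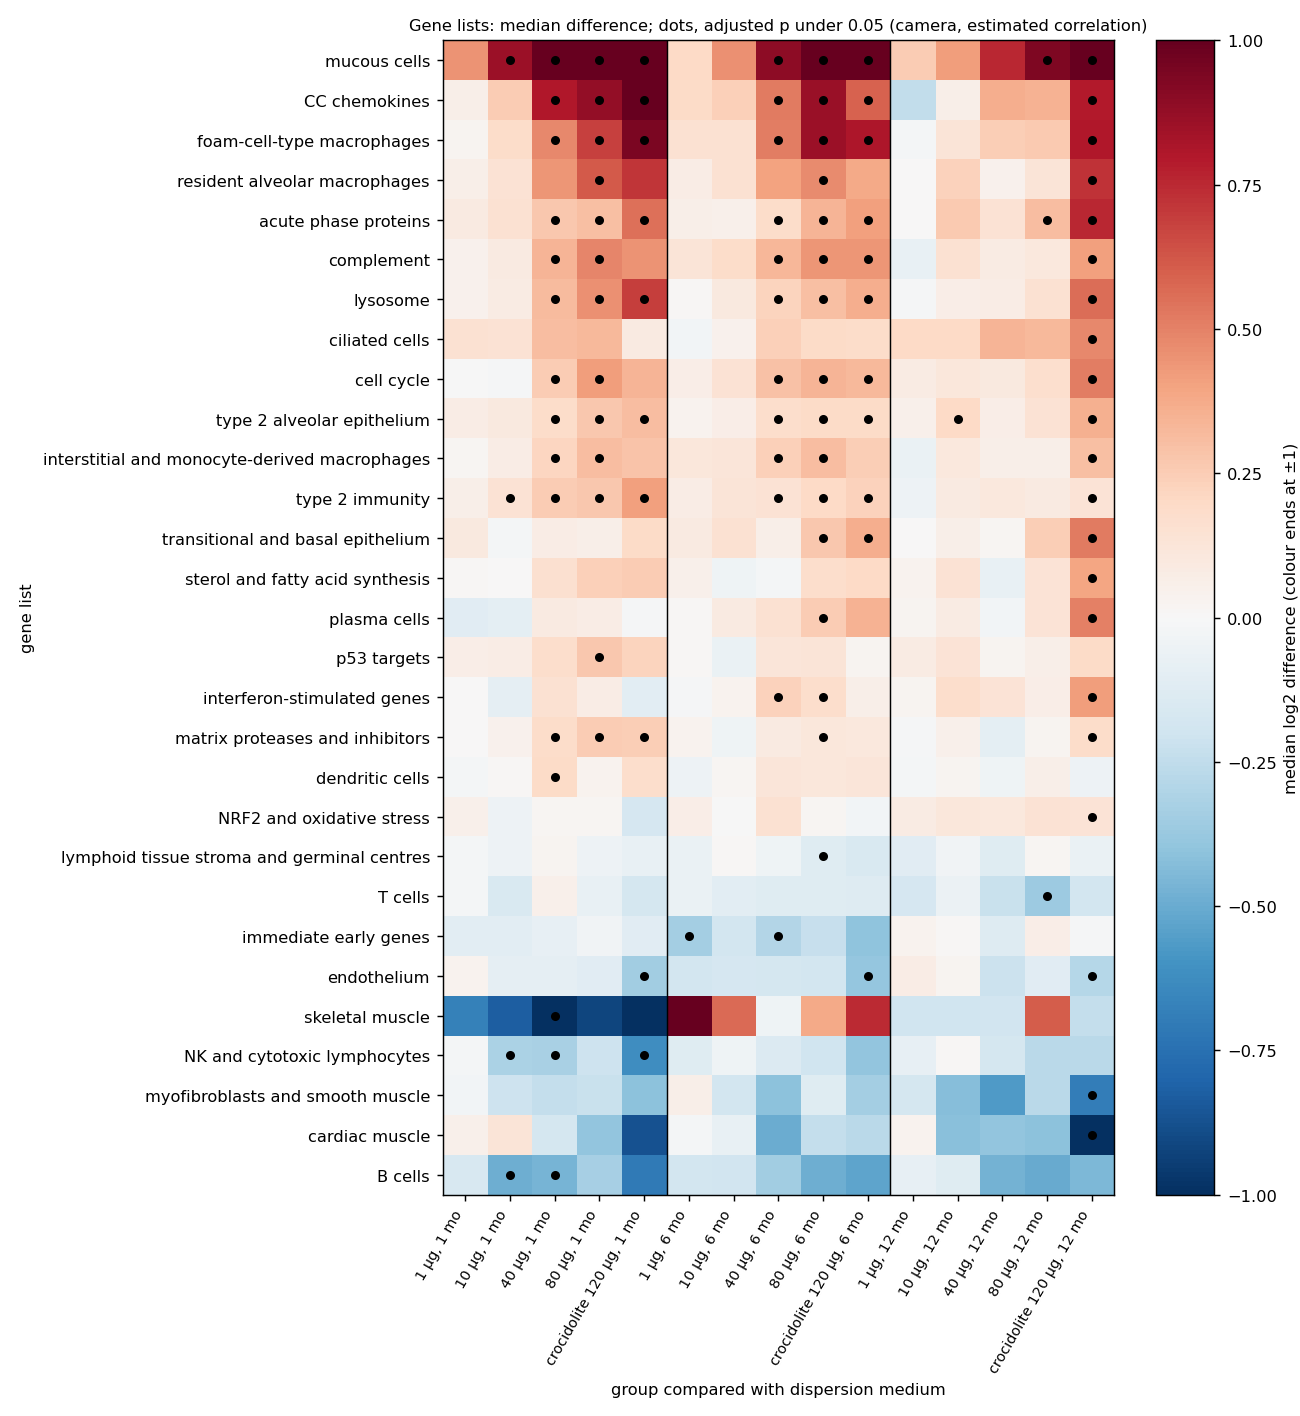
Median log2 difference from DM (colour) of each gene list (vertical axis) in each exposed group (horizontal axis), for the 29 lists with at least 1 black dot; dots mark an adjusted p under 0.05 by camera with an estimated correlation. Mucous cells are marked with 80 µg and with crocidolite at all 3 times.

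In the fibrillar collagens and matrix list 2 of 29 genes rose with 80 µg at 1 month, 3 adjusted over the list alone, namely Tnc, a matrix glycoprotein of injured tissue (0.67 ± 0.18), and fibronectin Fn1 (0.43 ± 0.12). At 6 months 1 of 29 rose, 1 higher and 1 lower adjusted over the list alone, Tnc at 0.64 ± 0.18. At 12 months limma called 0 of 29, also 0 adjusted over the list alone. At 1, 6 and 12 months the list had an adjusted p = 0.471, 0.587 and 0.695 with an estimated correlation. With crocidolite 4 of 29 were higher and 1 lower at 1 month, 5 and 1 adjusted over the list alone, with Col3a1, a fibrillar collagen, at 0.54 ± 0.17. At 6 months 2 were lower, 3 adjusted over the list alone, and at 12 months 1, 0 adjusted over the list alone (adjusted p = 0.723, 0.725 and 0.397 with an estimated correlation). Col1a1 had a mean of 8.76 ± 0.35 (SD, n = 8) in DM and 9.02 ± 0.19 with 80 µg at 1 month, and 8.04 ± 0.45 and 8.07 ± 0.41 at 12 months. The TGF-beta signalling list had 4 of 21 lower with crocidolite at 6 months, 5 adjusted over the list alone, and its call was lost (adjusted p = 0.163 with an estimated correlation).

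Set against each other, 80 µg MWCNT and crocidolite, which differ in mass as well as in kind, differed in 20 genes at 1 month, 6 at 6 months and 0.978% of genes at 12 months. At 12 months 33 were higher with MWCNT, or 15.2% of those called. Dmbt1 was lower with MWCNT by -2.57 ± 0.32, -3.24 ± 0.28 and -4.09 ± 0.29 at 1, 6 and 12 months, and Gp2 by -1.54 ± 0.30, -2.14 ± 0.26 and -3.13 ± 0.27. Fgg was lower at 12 months (-2.73 ± 0.32, adjusted p = 8.97e-11), and Ednrb higher at 1 month (0.72 ± 0.17, adjusted p = 0.0492). At 12 months mucous cells had 6 of 14 lower with MWCNT, 7 adjusted over the list alone, and lysosome 7 of 21, 16 adjusted over the list alone (adjusted p = 0.024 for each with an estimated correlation). Of acute phase proteins 4 of 14 were lower, 9 adjusted over the list alone (adjusted p = 0.00771 with an estimated correlation). Of 100 splits of the 1-month arrays, the real one included, 6 called as many genes. The 1-month share of 0.0902% became 0.23%, 1.19%, 0.766%, 0.0225% and 0.0135% without crocidolite replicates 1, 2, 3, 4 and 5. Without the word replacement 55, 12 and 501 genes passed at 1, 6 and 12 months, with it 0 at 1 month by limma and 71 at 12 months, and with it as a covariate 12, 6 and 250. Centring moved the share of higher genes at 12 months to 30%.

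Of genes called with each fibre, 305 were higher with both at 1 month, 151 at 6 months and 34 at 12 months, where independent lists would share 10.94, 2.58 and 1.51. Both comparisons use the same DM arrays, so part of this overlap may come from them. With the DM arrays split, 4 for each fibre, a median of 157.5, 45 and 9.5 genes were higher with both over 50 splits, against 4.23, 0.42 and 0.3 for independent lists. Unchanged groups simulated against shared DM arrays had 0 such genes in each of 100 draws per time, but few of these draws called any gene in limma, so they set no useful level. Mlph, Pigr, Cd68, Lgals3, Trem2, Ctsk, Clca1, Gpnmb, Muc5b, Mmp12 and Retnla, named here after their values were seen, were among 25 genes higher with both fibres at all 3 times. Across all genes the log2 differences correlated at 0.696, 0.727 and 0.553 at 1, 6 and 12 months, with genes not independent of each other. Unchanged groups simulated against shared DM arrays gave a mean of 0.449, 0.497 and 0.490 and reached 0.768, 0.781 and 0.759, above the observed values at each time. DM arrays split between the comparisons gave 0.415, 0.426 and 0.258. The covariances were 0.0494, 0.0370 and 0.0335, with split DM arrays 0.0349, 0.0261 and 0.0186, against a mean of 0.0152, 0.0145 and 0.0147 simulated.

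The response at 12 months was also compared with that at 1 month, where 28% of simulated 1.5-fold changes of the 80 µg effect were recovered. With 80 µg MWCNT limma called 2 genes, which had a smaller effect at 12 months, Chil4 by -4.60 ± 0.82 (adjusted p = 0.0025) and Scin, an actin-severing protein, by -1.79 ± 0.35 (adjusted p = 0.0134). The lists of type 2 immunity, with 1 of 18 called and 4 lower adjusted over the list alone, and T cells, with 0 of 18 called and 4 lower adjusted over the list alone, had a lower effect of 80 µg at 12 months (adjusted p = 0.049 for each with an estimated correlation). With crocidolite 8 genes had a higher and 4 a lower effect at 12 months. Of 100 splits of the same arrays, the real one included, 6 called as many. Those splits removed the fibre effect at both times, so they do not test a change between them. The fibrinogen chains Fga and Fgg were at 2.43 ± 0.49 and 2.04 ± 0.47 (adjusted p = 0.00956 and 0.0496). Pon1, which was lower with crocidolite at 1 month, was at 1.59 ± 0.26, so its positive value does not by itself mean a rise at 12 months. The effect was lower for Rnase2a, at -3.71 ± 0.70, Arg1 at -2.59 ± 0.51 and Corin, a protease of natriuretic peptides, at -1.55 ± 0.33. Fgg was not past the test with replacement as a covariate (1.97, adjusted p = 0.0569), after quantile normalization (1.93, adjusted p = 0.0609) or centring (1.98, adjusted p = 0.082), or when any 1 of the 5 crocidolite arrays of 1 month was left out (1.91 to 2.15, adjusted p from 0.0505 to 0.119). Arg1 and Corin were not past it without replicate 4 (-2.39 and -1.44, adjusted p = 0.0654 and 0.0807) or replicate 5 (-2.15 and -1.41, adjusted p = 0.119 and 0.12), nor was Fga without replicate 5 (2.41, adjusted p = 0.0531). The interferon-stimulated genes list had a higher crocidolite effect at 12 months, with 0 of 17 called by limma over all genes and 12 adjusted over the list alone (adjusted p = 0.00726 with an estimated correlation). So had club cells, with 2 of 11 called and 6 adjusted over the list alone (adjusted p = 0.00356 with an estimated correlation). The type 2 immunity list had a lower crocidolite effect, with 1 of 18 called and 2 adjusted over the list alone (adjusted p = 0.0261 with an estimated correlation). Across all genes, which are not independent, the effects at 1 and 12 months correlated at 0.225 with 80 µg and 0.564 with crocidolite. Such a correlation is also lower where effects are small against noise, so these values do not compare change over time between the fibres. Of genes higher at 1 month, 92.8% with 80 µg and 94% with crocidolite had the same direction at 12 months. Of genes lower at 1 month it was 50% of 24 and 91.7% of 628. The 12 crocidolite genes became 33, 30, 3 and 2 without the 1-month replicates 2, 3, 4 and 5, and in arrays without the word replacement 2 genes passed for each fibre. Chil4 and Scin were not past the test in those arrays (-3.51 ± 1.14 and -1.52 ± 0.49, adjusted p = 0.433 for each), nor in arrays with the word, where the differences were larger (-5.91 ± 1.01 and -2.01 ± 0.44, adjusted p = 0.0586 and 0.674). With accession order as a spline Scin was at -1.58 (adjusted p = 0.112) and Chil4 stayed past the test (adjusted p = 0.0131). Without the 9 arrays high in Krt4 limma called 0 genes for 80 µg, with Chil4 at -4.41 ± 0.90 (adjusted p = 0.0663) and Scin at -1.75 ± 0.38 (adjusted p = 0.0937).

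In DM mice 151 genes were higher and 97 lower at 12 than at 1 month. Phex, an endopeptidase, was at -1.38 ± 0.19 (adjusted p = 2.78e-07), Cyp1a1, a cytochrome P450 induced by aryl hydrocarbons, at -1.86 ± 0.45, and Il23r, a cytokine receptor of lymphocytes, at 1.09 ± 0.20. The fibrillar collagens and matrix list had 12 of 29 lower, 18 adjusted over the list alone (median -0.35, adjusted p = 0.00482 with an estimated correlation). Of ciliated cells genes 10 of 17 were higher, 16 adjusted over the list alone (adjusted p = 0.0203 with an estimated correlation). In arrays without the word replacement 64 genes passed, in those with it 1, and with it as a covariate 238. Centring moved the share of higher genes among those called from 60.9% to 49.4%.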

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

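All tests of explanations in this part were chosen only after the results were seen. Dixon's test for 1 value far from the rest, run on 186 sets of values, each a gene or score within a group, picked 25, where chance picks about 1 in 20, or 9.3. The sets included Krt4 and the response score, taken up for arrays already seen out of place. Several of the 25 can also come from the same mouse. The figure of 25 against 9.3 is thus no measure of an excess over chance.

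At 6 months replicate 7 of the 1 µg group stood far above the other mice of its group, with Mmp12 at 8.40 (others 4.93 to 5.47), Gpnmb at 8.79 (6.16 to 6.46), Timp1 at 5.40, Ccl22 at 6.04 and a response score, the mean level of the genes raised at least 1.5-fold by 80 µg at 1 month, of 6.27 (5.47 to 5.66). Replicate 7 of the 80 µg group scored 5.53, inside the DM range of 5.29 to 5.74, while the other 80 µg mice scored 5.78 to 7.26. A failed delivery to the 80 µg mouse alone leaves the 1 µg mouse unexplained, whose gap of 0.61 to the next compares with an SD of 0.076, and poor arrays are argued against by a lower median correlation of 0.959 with all others. An exchange of the labels of these mice could account for both, since a partner lies out of place in each group, but no label was changed. Without these 2 arrays the dose trend at 6 months called 2.22% of genes in place of 1.34%.

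Krt4, a keratin of squamous epithelium that lines the mouth and oesophagus, was at 10.83 in replicate 8 of crocidolite at 6 months, 12.11 in replicate 2 of DM at 1 month, 11.89 in replicate 4 of 1 µg at 1 month, 11.24 in replicate 4 of 80 µg at 1 month and 11.84 in replicate 3 of 80 µg at 6 months. High levels also stood in replicates 3 and 8 of 1 µg at 6 months and replicates 1 and 5 of 80 µg at 12 months, whereas no other array exceeded 4.60. A change of lung epithelium by the fibres is argued against by the DM array at 12.1. A second set of 10 squamous epithelium genes and the skeletal muscle list both lay above the 95th percentile of the other arrays. This held in 9 of the 9 arrays high in Krt4. Squamous and muscle genes had already marked these arrays, so it is no separate test. Tissue of another organ in the sample, possibly oesophagus, could account for the pattern. Muscle also occurred apart from squamous genes, with Acta1, a skeletal muscle actin, at 9.56 in replicate 7 of 10 µg at 6 months and 9.31 in replicate 8 of DM at 1 month, where Krt4 was low, and which organ it was, and any biological cause within the design, was not tested.

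Cardiac muscle genes were lower with crocidolite at 12 months, with a list median of -1.12. Dilution of all lung cells by other cells is argued against by the type 1 alveolar epithelium list, whose median was 0.106. Across the 13 cardiac genes, which are not independent, the fall followed how strongly each gene varied with the rest of the list within the other 16 groups (Pearson's r 0.869, Spearman's rho 0.824), so less cardiac muscle in the tissue taken is a candidate explanation. The myofibroblasts and smooth muscle list (8 of 12 lower, median -0.69) and the endothelium list (7 of 18 lower, median -0.29) were lower too, which less cardiac muscle was not tested to explain. Lower expression within the muscle was not tested and stays open.

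Other values far from their groups, with no explanation tested, were Saa3 at 7.72 in replicate 2 of 40 µg at 12 months, 7.31 in replicate 8 of 80 µg at 12 months and 9.50 in replicate 2 of 80 µg at 6 months. Mmp12 was at 5.16 in replicate 4 of 10 µg at 12 months. Timp1 was at 5.52 in replicate 8 of 40 µg at 6 months and 5.84 in replicate 8 of 80 µg at 12 months, a mouse with Ccl22 at 6.94. Col1a1 was at 9.59 in replicate 4 of crocidolite at 1 month, 8.51 in replicate 3 of 1 µg at 12 months and 8.99 in replicate 5 of 80 µg at 12 months. Lcn2 was at 10.74 in replicate 2 and Muc5b at 8.62 in replicate 7 of crocidolite at 12 months. Ccl22 was at 5.38 in replicate 2 of 1 µg at 12 months, and Cxcl5 at 7.34 in replicate 6 of 10 µg at 12 months and 4.46 in replicate 1 of 80 µg at 1 month.

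The effect at 12 months differed from that at 1 month, by an interaction in limma, for Chil4 (-4.60) and Scin (-1.79) with 80 µg, and neither passed without the 9 arrays high in Krt4, though the differences hardly moved (-4.41 and -1.75, adjusted p = 0.0663 and 0.0937). With crocidolite it differed for Rnase2a (-3.71), Arg1 (-2.59), Corin (-1.55), Pon1 (1.59), Fga (2.43), Fgg (2.04) and Gabrp (0.90). For crocidolite chance was not excluded, and 6 of 100 splits of the arrays gave as many genes. Those splits removed the fibre effect at both times, so they cannot test a change between them. The crocidolite genes, 12 in all, became 2 without replicate 5 and 3 without replicate 4 of crocidolite at 1 month.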

How the results depend on the processing

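Leaving out 3 sets of doubtful arrays and the cardiac muscle covariate were chosen only after the results were seen, and the other alternatives were planned. Values are the share of the 22180 genes past the limma test, or numbers of lists, and those that moved by more than 1.5 times are given. They stand against shares at 1 month of 0%, 0.0225%, 0.573%, 1.79%, 5.76%, 0.0902% and 3.03% for 1, 10, 40 and 80 µg, crocidolite, 80 µg against crocidolite and the dose trend. At 6 months these were 0%, 0.00451%, 0.212%, 0.933%, 3.68%, 0.0271% and 1.34%. At 12 months these were 0%, 0%, 0.0361%, 0.176%, 6.47%, 0.978% and 1.2%. The time differences stood at 0.00902% for MWCNT and 0.0541% for crocidolite, and DM over time at 1.12%. Camera had called 7, 21, 27, 27 and 28 lists at 1 month for 1, 10, 40 and 80 µg and crocidolite. At 6 months these were 17, 20, 29, 29 and 25, and at 12 months 7, 17, 19, 22 and 28. For 80 µg against crocidolite it had called 12, 11 and 24 lists at 1, 6 and 12 months and for the dose trend 27, 33 and 26. It had called 17 for the MWCNT time difference, 14 for the crocidolite time difference and 15 for DM over time. For 1 µg the counts of genes at an unadjusted p under 0.05 were 437, 1249 and 595, and for 10 µg at 12 months 945. Only 1249 is above the share of 0.05 of the genes that chance would give on average, and with genes not independent that is no test of an effect. With replacement as a covariate the shares were 0.0135% for 10 µg and 0.0541% for 80 µg against crocidolite at 1 month. The 12-month values were 0.135% for 40 µg. Among arrays without the word replacement the shares were 0.00902% for 10 µg, 0.207% for 40 µg, 0.343% for 80 µg, 1.8% for crocidolite, 0.248% for 80 µg against crocidolite and 1.17% for the dose trend at 1 month. Those at 6 months were 0.135% for 40 µg, 0.266% for 80 µg, 0.0541% for 80 µg against crocidolite and 0.748% for the dose trend. For 12 months these became 2.44% for 40 µg, 0.965% for 80 µg, 2.91% for crocidolite, 2.26% for 80 µg against crocidolite and 1.82% for the dose trend. The time comparisons gave 0.00902% for the crocidolite time difference and 0.289% for DM over time. Among arrays with the word the shares were 0.667% for 80 µg, 1.18% for crocidolite and 0% for 80 µg against crocidolite at 1 month. By 12 months there were 0.00902% for 40 µg, 0.0225% for 80 µg, 1.3% for crocidolite, 0.32% for 80 µg against crocidolite and 0.0316% for the dose trend. In comparisons of times came 0% for the MWCNT time difference, 0% for the crocidolite time difference and 0.00451% for DM over time. With accession order as a spline the shares were 0.307% for 80 µg, 0.591% for 80 µg against crocidolite and 2.52% for the dose trend at 12 months. Over time they were 0.00451% for the MWCNT time difference, 0.0857% for the crocidolite time difference and 1.83% for DM over time. Fitted on the arrays of the time point the shares were 0.0451% for 10 µg and 0.0271% for 80 µg against crocidolite at 1 month. At 6 months they were 0% for 10 µg and 0.0586% for 40 µg. The 12-month values were 0.0676% for 40 µg. Fitted on the groups compared the shares were 0.0361% for 10 µg, 1.63% for crocidolite and 0.00902% for 80 µg against crocidolite at 1 month. Those at 6 months were 0.108% for 80 µg. For 12 months these became 0.0947% for 80 µg, 0.302% for 80 µg against crocidolite and 0.735% for the dose trend. The time comparisons gave 0.0451% for the MWCNT time difference and 0.541% for DM over time. Among genes above the median level, with calls still divided by all 22180 genes, the shares were 0.00902% for 1 µg and 0% for 80 µg against crocidolite at 6 months. By 12 months there were 0.185% for 40 µg. In comparisons of times came 0% for the MWCNT time difference. After quantile normalization the shares were 0.0586% for 80 µg against crocidolite at 1 month. At 6 months they were 0.00451% for 1 µg and 0.00902% for 10 µg. The 12-month values were 0.0631% for 40 µg. Over time they were 0.0857% for the crocidolite time difference. After centring arrays the shares were 0.00451% for 1 µg at 6 months. Those at 12 months were 0.153% for 40 µg and 0.298% for 80 µg. The time comparisons gave 1.89% for DM over time. With each of the 41345 features tested, the features called, divided by the 22180 genes, gave 0.0135% for 10 µg at 1 month. With array weights the shares were 2.84% for 80 µg, 3.66% for crocidolite, 0.0406% for 80 µg against crocidolite and 5.06% for the dose trend at 1 month. For 6 months these became 0.00902% for 10 µg, 2.34% for 80 µg, 7.15% for crocidolite, 0.0451% for 80 µg against crocidolite and 3.13% for the dose trend. By 12 months there were 3.14% for 40 µg, 0.573% for 80 µg, 10.3% for crocidolite and 5.08% for the dose trend. In comparisons of times came 0.0586% for the MWCNT time difference and 2.48% for DM over time. With trended and robust moderation the shares were 0.00902% for 1 µg at 6 months. At 1.5-fold or more the shares were 1.05% for 80 µg, 3.08% for crocidolite and 1.04% for the dose trend at 1 month. At 6 months they were 1.37% for crocidolite and 0.649% for the dose trend. The 12-month values were 3.12% for crocidolite, 0.609% for 80 µg against crocidolite and 0.379% for the dose trend. Over time they were 0.613% for DM over time. At an adjusted p under 0.01 the shares were 0.0135% for 10 µg, 0.361% for 40 µg, 1.1% for 80 µg, 3.16% for crocidolite, 0.018% for 80 µg against crocidolite and 1.78% for the dose trend at 1 month. Those at 6 months were 0.0947% for 40 µg, 0.464% for 80 µg, 1.51% for crocidolite and 0.757% for the dose trend. For 12 months these became 0.018% for 40 µg, 0.0766% for 80 µg, 3.65% for crocidolite, 0.374% for 80 µg against crocidolite and 0.325% for the dose trend. The time comparisons gave 0.00451% for the MWCNT time difference, 0.0271% for the crocidolite time difference and 0.388% for DM over time. With the most variable feature per gene the shares were 0.0451% for 80 µg against crocidolite at 1 month. Without 2 arrays out of place at 6 months the shares were 2.22% for the dose trend at 6 months. Without 9 arrays high in Krt4 the shares were 0.018% for 80 µg against crocidolite at 1 month. By 6 months there were 2.18% for crocidolite. At 12 months they were 0.622% for 80 µg against crocidolite and 1.91% for the dose trend. In comparisons of times came 0% for the MWCNT time difference. Without 10 arrays of low correlation the shares were 0.0135% for 10 µg, 3.63% for crocidolite and 0.0271% for 80 µg against crocidolite at 1 month. The 6-month values were 0.00902% for 10 µg. Those at 12 months were 0.379% for 40 µg, 0.361% for 80 µg, 0.618% for 80 µg against crocidolite and 2.52% for the dose trend. Over time they were 0.0316% for the MWCNT time difference and 0.0271% for the crocidolite time difference. With an estimated correlation the lists called were 0 for 1 µg, 4 for 10 µg, 15 for 40 µg, 13 for 80 µg and 10 for crocidolite at 1 month. For 6 months these became 1 for 1 µg, 0 for 10 µg, 12 for 40 µg, 16 for 80 µg and 11 for crocidolite. By 12 months there were 0 for 1 µg, 1 for 10 µg, 0 for 40 µg and 3 for 80 µg. For 80 µg against crocidolite 0, 0 and 8 lists were left at 1, 6 and 12 months, for the dose trend 15, 15 and 5, for the MWCNT time difference 2, for the crocidolite time difference 3 and for DM over time 3. With fry the lists called were 0 for 1 µg, 4 for 10 µg and 17 for 80 µg at 1 month. At 6 months they were 1 for 1 µg, 0 for 10 µg, 14 for 40 µg and 19 for 80 µg. The 12-month values were 0 for 1 µg, 1 for 10 µg and 6 for 40 µg. It called 3 and 0 for 80 µg against crocidolite at 1 and 6 months, 14 for the dose trend at 12 months, 2 for the MWCNT time difference, 3 for the crocidolite time difference and 3 for DM over time. Without 2 arrays out of place at 6 months the lists called were 8 for 1 µg at 6 months. Leaving out each crocidolite array of 1 month gave 2.83% to 7.61% for crocidolite, 0.0135% to 1.19% for 80 µg against crocidolite and 0.00902% to 0.149% for the crocidolite time difference. The lowest of each came without replicate 5 and the highest without replicate 2. Among 6988 values of named genes under the alternatives 6085 kept their direction and passed, 901 kept it and no longer passed, and 2 reversed. Direction could not change where only the thresholds, the moderation, the genes tested or the groups fitted differed, since the estimate stays the same. The genes were also picked for large differences in these data, so the few reversals are no measure of robustness. Arid3b at 40 µg and 1 month went from -0.51 to 0.11 with its most variable feature, a different feature of the gene. Ckmt2 with crocidolite at 12 months went from -1.30 to 0.003 with the cardiac muscle mean as a covariate. For stricter thresholds the smaller counts follow from the construction, and for the other settings, fewer arrays included, the cause was not tested. No paired analysis was possible because each mouse, by its number in the labels, belongs to a single group. Signal over background was not used here, so its limit on dim genes was not measured. Some leading genes were dim in controls, such as Saa3 with a mean of 3.92 in DM at 1 month, below the lowest array median of 4.009. The size of such differences rests on those dim control levels.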

Other observations

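The predictions for the splits of the arrays, and the choice of the genes named, came only after the results were seen, while the limma tests and the endothelium list were planned.

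Named here after their values were seen, 4 genes of blood vessel lining were lower after crocidolite at each time. Of these Kdr and Cdh5 belong to the endothelium list, of which 9, 10 and 7 of 18 genes were lower at 1, 6 and 12 months, and Eng and Plvap do not. Kdr, a VEGF receptor, was at -0.67, -0.56 and -0.48 at 1, 6 and 12 months, Eng, a co-receptor for TGF-beta family ligands, at -0.78, -0.55 and -0.50, and Plvap, a protein of endothelial fenestrae, at -0.67, -0.72 and -0.57. The junction protein Cdh5 was at -0.37, -0.28 and -0.27. All of these passed limma with all genes tested.

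Splits of the same arrays into other groups of the same sizes, 100 per comparison with the real one included, tested whether chance could be excluded. Each is given as the share of the 22180 genes past limma, the highest share of the other splits, and the number of splits as large. Chance counts as excluded where under 5 of 100 splits were as large, with no adjustment over the 24 comparisons, and in 7 of the 17 so excluded another split called more genes than the real one. By that limit it was excluded at 1 month for 10 µg (0.0225%, highest other 0.0631%, 2 as large), 40 µg (0.573%, highest other 0.18%, 1 as large) and 80 µg (1.79%, highest other 0.482%, 1 as large), and for crocidolite (5.76%, highest other 7.99%, 2 as large) and the dose trend (3.03%, highest other 0.00451%, 1 as large). At 6 months it was excluded for 40 µg (0.212%, highest other 0.00451%, 1 as large), 80 µg (0.933%, highest other 0.978%, 2 as large) and crocidolite (3.68%, highest other 0.699%, 1 as large), and for 80 µg against crocidolite (0.0271%, highest other 0.338%, 4 as large) and the dose trend (1.34%, highest other 0.113%, 1 as large). At 12 months it was excluded for 40 µg (0.0361%, highest other 0.171%, 3 as large), 80 µg (0.176%, highest other 0.239%, 2 as large) and crocidolite (6.47%, highest other 2.14%, 1 as large), and for 80 µg against crocidolite (0.978%, highest other 0.685%, 1 as large) and the dose trend (1.2%, highest other 0.415%, 1 as large). So it was for DM over time (1.12%, highest other 0.00902%, 1 as large). The MWCNT time difference fell under the same limit (0.00902%, highest other 0.0135%, 2 as large). For the time differences, treatments were reshuffled within each time, which removes the fibre effect at both times. Those splits thus cannot show whether the effect changed between 1 and 12 months.

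Chance was not excluded for 10 µg at 6 months (0.00451%, highest other 0.00451%, 6 as large). It was not excluded either for 80 µg against crocidolite at 1 month (0.0902%, highest other 4.04%, 6 as large) and the crocidolite time difference (0.0541%, highest other 4.85%, 6 as large), where the limit just given for time differences applies. The highest splits of these 2 comparisons, of 80 µg against crocidolite at 6 months and of 40 µg at 12 months called several times the real share, while the median of the other splits was 0 in each. Such splits may reflect a structure of the samples, which was not tested. For 1 µg at each time and 10 µg at 12 months limma called 0 genes. At an unadjusted p under 0.05 were 437, 1249, 595 and 945, of which only 1249 is above the share chance would give on average. With genes not independent, that is no test of an effect. With 0 genes called, all 100 splits are as large by construction, so the splits say nothing about chance there. The highest others were 0.00451%, 0.0812%, 0.00451% and 0.00902%.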
